A study of Cryptococcus neoformans with 16 samples.

How the data were processed

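The data came from 16 deposited RNA sequencing libraries of Cryptococcus neoformans H99, made from total RNA of liquid cultures and read on an Ion Torrent instrument, per the labels' protocols. The authors deposited a table of estimated counts, whole-number read counts per gene, for 6975 genes and 16 columns, and a pair of tables of low against high nitrogen at 30 °C and 37 °C. The submitters' processing notes name FastQC, HISAT2 2.1.0, StringTie 1.3.3b and DESeq2 1.20.0 without saying what each did. Per the file headers, the deposited tables of the authors give a log2 fold change with its standard error for each transcript. Per the file headers, these deposited tables also give a p-value and a q-value per transcript, and a signal column with the mean normalised count over all libraries. The genome build and gene annotation behind the counts are not given in the sources used here, nor is whether counting used the strand. Reads of near-identical paralogs, of overlapping genes and of antisense pairs could therefore not be told apart, and values of such genes are uncertain.

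Samples were grouped by the nitrogen level and temperature in their titles. The HN37 columns of replicates 1 and 3 were identical in every gene and were counted as 1 library, called replicate 1. The fixed design had named 16 libraries with 12 residual degrees of freedom, and 15 libraries with 11 were used. The authors' own fit appears to have held both columns. Mean counts from DESeq2 run here were set against those in the authors' deposited table over 5857 abundant loci with 1 transcript. Their log2 ratio scattered less with 16 columns (scaled median absolute deviation 0.00288) than with 15 libraries (0.0286). The authors' fold changes had the opposite sign to the file titles, with Pearson's r of -0.982 at 30 °C and -0.996 at 37 °C across 6135 loci with 1 transcript, against the fold changes computed here. In the authors' deposited table a positive value is thus higher in high nitrogen. All directions in the text are low minus high nitrogen, or 37 °C minus 30 °C, from the counts.

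Fold changes were computed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 6884 genes, and 32 genes had no count in any library. Libraries were scaled with TMM factors, which ran from 0.577 to 1.38. One quasi-likelihood model with 4 group means gave the 5 comparisons (low against high nitrogen at each temperature, their difference, and 37 °C against 30 °C at each nitrogen level). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.251. Log2 fold changes are given with standard errors and CPM as mean ± SD over libraries. With totals from 17517723 to 24481194 counts, 1 CPM stands for about 20 counts, so counting error is small beside the spread between libraries for abundant genes. For groups near the floor counting error is not small beside that spread. Among the genes named these include CNAG_07869 in LN30 (0.751 ± 0.574 CPM), CNAG_01075 in HN37 (1.12 ± 0.321 CPM) and CNAG_06312 in HN30 (2.43 ± 0.186 CPM). The depth also limits the mitochondrial genes, most of which lay at a few CPM or less.

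Lists of loci were fixed before the data were examined. They covered nitrogen assimilation and regulation, nitrogen source transport and catabolism, capsule, melanin, ergosterol synthesis, phospholipase, iron and copper uptake, oxidative stress, heat shock chaperones, drug efflux, mating, and mitochondrially encoded genes. The functions of the 41 loci outside the mitochondrial genome come from general knowledge of this strain, since neither the files nor the reference table gives products. The reference table, of assembly CNA3, held 8338 genes whose symbol was the locus tag in every case. It matched 6975 of 6975 genes of the count table and all 7773 transcript accessions, and served only for names, for the mitochondrial molecule and for which genes neighbour each other. Lists that needed product descriptions, such as ribosomal proteins, amino acid synthesis and ribosomal RNA, were not run. Lists with 5 or more tested genes were tested with camera in limma 3.58.1 (log2 CPM with prior count 2, preset correlation 0.01). An estimated correlation and the rotation test fry served as alternatives. List tests of the interaction and of the temperature comparisons were added to those planned.

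The genes named were the fixed loci and, for each comparison, the genes that rose or fell most among those called with an average log2 CPM of 3 or more and no overlap between the groups. Without product descriptions the rule fell back to 2 genes that rose and 2 that fell. For the interaction these were the genes with the smallest adjusted p in each direction. Locus tags are printed without symbols. Genes outside the fixed lists are called genes without a named product because the sources used here gave none, which does not mean that their products are unknown.

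Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter or a mean CPM of 10 or more, a fit of only the libraries compared, a fold change of 2 or more, blocks for the replicate number and for the letter in the sample titles, and leaving out each library. Those added later were all 16 columns, other numbers or letters for the merged library, the main within-group axis as a covariate, leaving out HN30 replicate 3 and HN37 replicate 2 together, and limma-voom with a spread per group. Other splits of the libraries into groups of the same sizes were counted for each comparison (all 35 splits, or 100 drawn for the interaction). The model was tested on simulated counts with the real means and library sizes and a spread set per temperature. With no changed genes, 11 of 20 simulated sets gave a call at 30 °C (at most 10 genes), 2 of 20 at 37 °C (at most 1) and 1 of 20 for the interaction (at most 2). Each simulated gene was drawn independently of the others. In the real libraries the main within-group axis held 47.3% of the variance of deviations from the group means. The simulations lack such shared variation and cannot show how many false calls it gives. Library measures were compared with exact permutation tests, 2-sided, over 12 comparisons. Principal components were computed from log2 CPM.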

Results

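Gene expression was measured by RNA sequencing in Cryptococcus neoformans H99, a reference strain of this encapsulated pathogenic yeast. The cells grew in a defined carbon base with ammonium chloride as the nitrogen source, at 0.53 g/L (high nitrogen, HN) or 0.21 g/L (low nitrogen, LN). Cultures at 30 °C grew for 38 h and cultures at 37 °C for 28 h, so temperature and culture time changed together. The labels give 4 biological repeats in each of the 4 groups, named here HN30, LN30, HN37 and LN37. Of the 16 deposited libraries, HN37 replicates 1 and 3 held the same count in 100% of 6975 genes, whereas other pairs within a group matched in 1.1% to 1.58%. These columns were counted as 1 library (HN37 replicate 1), which left n = 3 in HN37 and n = 4 in the other groups. Total counts per library were 20200000 ± 1520000 in HN30, 20300000 ± 1260000 in LN30, 22600000 ± 2430000 in HN37 and 20000000 ± 2120000 in LN37 (mean ± SD), and single libraries held from 17517723 to 24481194.

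The nitrogen groups lay apart along the second principal component, and the LN groups at the 2 temperatures along the first. The first component held 53.1% of the variance and the second 21.6%. HN30 was the most scattered group, with a mean first-component score of -10.3 ± 33.1 (SD, n = 4). Its replicate 3 scored -56.8, beside -4.14, -1.86 and 21.6 in the others. That library also had the lowest TMM factor, 0.577, and its 10 most abundant genes took 13.3% of its counts, the most of the 15 libraries. The 10 most abundant genes took 6.86% ± 0.361 of the counts in LN37 and 8.64% ± 0.433 in HN37. This difference had an exact permutation p (2-sided) of 0.0286, the smallest that 35 arrangements allow, and a Benjamini-Hochberg value of 0.0858 over 12 comparisons.

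**Figure D1:**
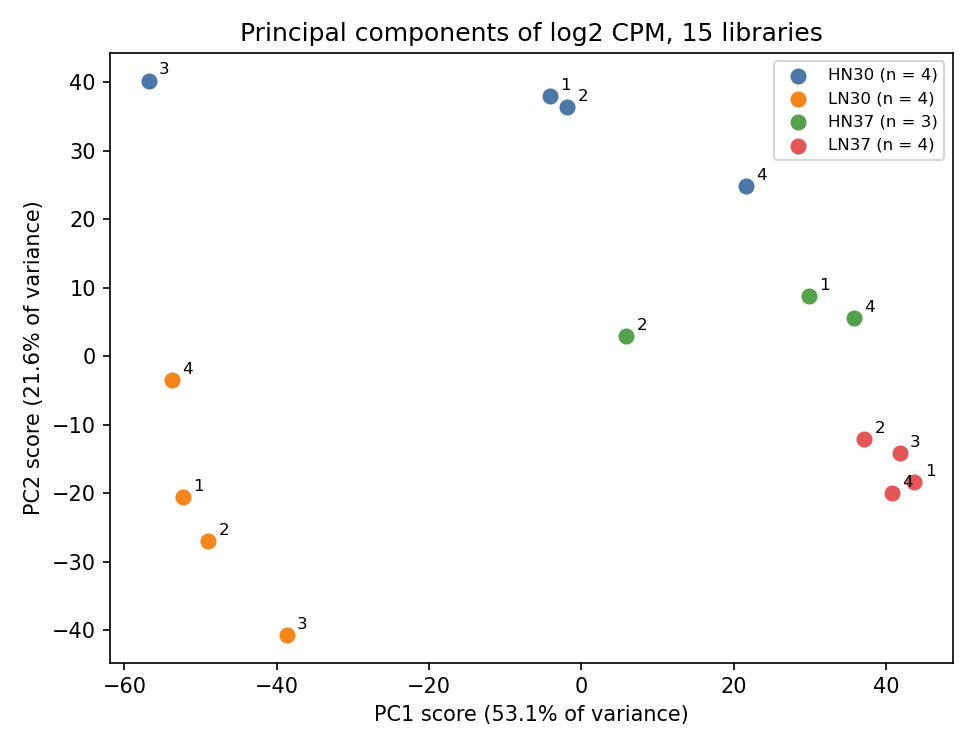
Principal components of log2 CPM for 15 independent libraries, first component on the x axis (53.1% of variance) and second on the y axis (21.6%), coloured by group. LN30 and LN37 lie far apart along the first component, and HN30 replicate 3 lies at -56.8, away from the rest of its group.

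Low against high nitrogen at 30 °C asks how the yeast's transcripts respond to a limited ammonium supply. Both ammonium permease loci rose. CNAG_00235 went from 95.7 ± 37.9 CPM in HN30 to 697 ± 284 in LN30 (mean ± SD, n = 4 each), a log2 fold change of 2.86 ± 0.30 (SE; adjusted p = 1.08e-05). CNAG_04758 went from 20.7 ± 21.3 to 318 ± 61.8 CPM, a log2 fold change of 3.93 ± 0.49 (adjusted p = 3.5e-05), and 4.98 without HN30 replicate 4. The NADP-dependent glutamate dehydrogenase locus CNAG_01577, which assimilates ammonium, rose by a log2 fold change of 1.99 ± 0.40 (adjusted p = 0.001), while the NAD-dependent enzyme's locus CNAG_00879 had -1.54 ± 0.27 (adjusted p = 0.000335). Of the ergosterol synthesis loci 5 of 8 were lower in LN30, and of the capsule loci 5 of 6, although neither list passed camera with an estimated correlation (adjusted p = 0.69 for both). Both laccase loci, whose enzymes make melanin, were higher.

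Of the 9 nitrogen loci fixed beforehand, 5 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone. In the assimilation and regulation list 2 of 5 rose and 1 fell, in the transport list both loci rose, and in the catabolism list 1 of 2 rose. The GATA-type nitrogen regulator CNAG_00193 rose by a log2 fold change of 0.96 ± 0.18 (adjusted p = 0.000565) and the urate oxidase locus CNAG_04307 by 1.37 ± 0.20 (adjusted p = 8.4e-05). The urease locus CNAG_05540 had 0.52 ± 0.23 (adjusted p = 0.0706), but was called without HN30 replicate 3 (0.84). Glutamine synthetase (CNAG_00457) and glutamate synthase (CNAG_04862) did not pass the test, with log2 fold changes of 0.18 ± 0.17 and 0.33 ± 0.44.

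**Figure D2:**
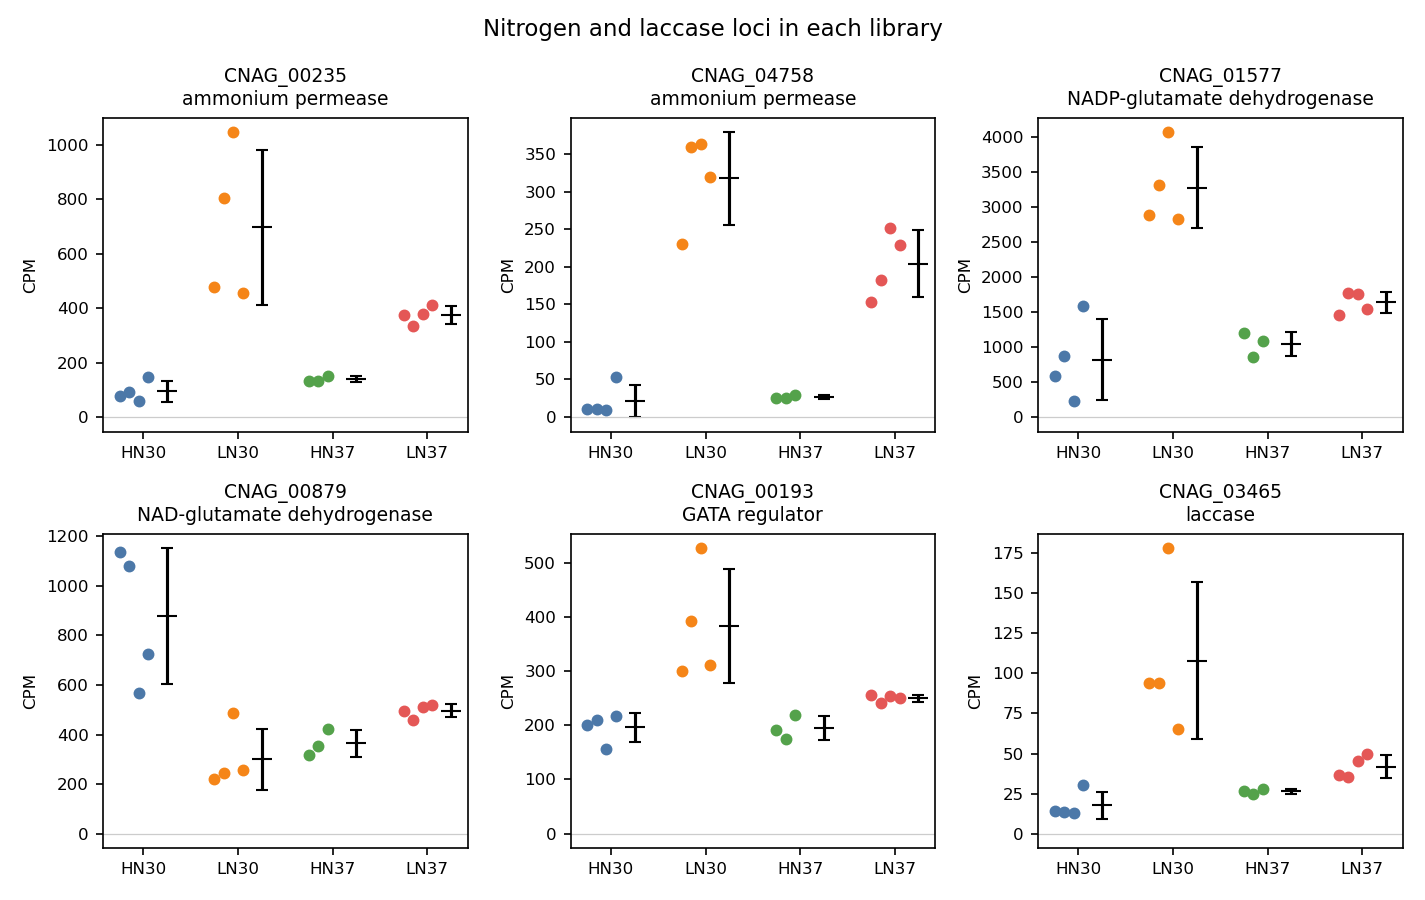
Normalised CPM (y axis) of 6 loci in each library of HN30, LN30, HN37 and LN37 (points), with the mean and SD of each group (n = 4, 4, 3 and 4). The permeases CNAG_00235 and CNAG_04758 were higher in low nitrogen at both temperatures, whereas the NAD-dependent dehydrogenase CNAG_00879 was lower in LN30 (301 ± 123 CPM) than in HN30 (878 ± 275 CPM).

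Both melanin loci rose, with laccase CNAG_03465 going from 17.7 ± 8.4 to 108 ± 48.9 CPM (log2 fold change 2.60 ± 0.32, adjusted p = 2.85e-05) and CNAG_03464 changing by 1.44 ± 0.36 (adjusted p = 0.00403). In ergosterol synthesis 5 of 8 loci fell and none was called higher, also when adjusted over the list alone. They were CNAG_00854 (-2.68 ± 0.36), CNAG_00519 (-1.89 ± 0.19), CNAG_03819 (-1.66 ± 0.29), CNAG_01737 (-1.39 ± 0.26) and the lanosterol demethylase CNAG_00040 (-1.06 ± 0.30), on the log2 scale, and CNAG_06829 was called lower without LN30 replicate 3 (-0.88). As a list, ergosterol synthesis had a camera adjusted p of 0.033, but adjusted p = 0.69 with an estimated correlation. The list call also ended without HN30 replicate 2 (0.0775), LN30 replicate 1 (0.0568) or LN30 replicate 4 (0.0671), within a leave-one-out range of 0.00543 to 0.0775. Of 6 capsule loci, 5 fell, again also when adjusted over the list alone, from -0.44 ± 0.16 at CNAG_03322 to -1.29 ± 0.25 at CNAG_02885. The capsule list had a camera adjusted p of 0.0589, and adjusted p = 0.69 with an estimated correlation, but passed the rotation test fry (0.00667) and camera without HN30 replicate 3 (0.0187) or LN30 replicate 3 (0.0393), within a range of 0.0187 to 0.112. Fitted on the 30 °C libraries alone, all 5 ergosterol calls stood and 2 of the 5 capsule calls, those of CNAG_02885 and CNAG_07554. The capsule call of CNAG_04969 ended without HN30 replicate 1 (-0.61) or 2 (-0.51) or LN30 replicate 1 (-0.58). That of CNAG_03322 ended without HN30 replicate 1 (-0.42) or 2 (-0.34) or LN30 replicate 1 (-0.38) or 2 (-0.43).

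Iron and copper loci were split, with 3 of 8 higher and 1 lower over all genes and adjusted over the list alone. The metallothionein CNAG_05449 rose by a log2 fold change of 2.28 ± 0.60 (adjusted p = 0.00603), which was 3.43 without HN30 replicate 3. The metallothionein CNAG_00306 had 0.93 ± 0.28 (adjusted p = 0.0132) and lost its call without LN30 replicate 1 (0.76). The siderophore transporter CNAG_00815 had 1.0 ± 0.33 (adjusted p = 0.0216). Its call ended without HN30 replicate 1 (0.84), 2 (0.91) or 4 (0.84) or LN30 replicate 1 (0.91) or 2 (0.89), and it had 1.52 without HN30 replicate 3. The locus CNAG_01653 had -2.20 ± 0.81 (adjusted p = 0.0357). Its call ended without HN30 replicate 1 (-2.24), 2 (-2.26) or 4 (-1.94) or LN30 replicate 1 (-2.32) or 2 (-2.16). LN30 replicate 3 held 20 CPM of it, beside 1350 to 2670 in the other LN30 libraries, and limma-voom gave -3.41 and the block for the title letter -2.85, whereas limma-voom with a spread per group ended the call, as did that block with the merged library lettered D (-2.5). The calls of CNAG_00815 and CNAG_01653 also ended when the 30 °C libraries were fitted alone. The list had a camera adjusted p of 0.435, as did the mitochondrially encoded genes and the nitrogen assimilation list, and 0 of 9 tested mitochondrial genes passed (camera unadjusted p = 0.435, fry adjusted p = 0.492). Without HN30 replicate 3, however, CNAG_09004 (1.77), CNAG_09006 (1.49) and CNAG_09009 (1.0) were called higher.

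In the remaining lists, the counts were the same over all genes and adjusted over the list alone. The efflux transporter CNAG_00730 rose (0.83 ± 0.21, adjusted p = 0.00516), as 1 of 2 efflux loci, and neither superoxide dismutase locus passed the test, although CNAG_04388 was called lower without LN30 replicate 4 (-0.98). One of 2 chaperone loci, CNAG_06443, had -0.71 ± 0.27 (adjusted p = 0.0414), and its call ended in 6 of the 8 leave-one-out fits. These were the fits without HN30 replicate 1 (-0.76), 2 (-0.71) or 4 (-0.65) and without LN30 replicate 1 (-0.63), 2 (-0.66) or 4 (-0.67). The phospholipase B locus CNAG_06085 had 0.75 ± 0.26 (adjusted p = 0.0272), and lost its call without HN30 replicate 1 (0.64), 2 (0.67) or 4 (0.59) or LN30 replicate 1 (0.76) or 2 (0.73), with 1.2 without HN30 replicate 3. The pheromone receptor CNAG_06808, the only mating locus on the list, had 0.55 ± 0.18 (adjusted p = 0.0192) and lost its call without HN30 replicate 1 (0.52), 2 (0.50) or 4 (0.41). The efflux call stood when the 30 °C libraries were fitted alone, whereas the calls of CNAG_06085 and CNAG_06808 ended.

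The genes without a named product that changed most at 30 °C were CNAG_01118 and CNAG_06312, which rose, and CNAG_04468 and CNAG_06554, which fell. CNAG_01118 went from 10.3 ± 7.5 to 1780 ± 1230 CPM, a log2 fold change of 7.41 ± 0.63 (adjusted p = 3.22e-06), and 8.05 without HN30 replicate 4. CNAG_06312 had 5.41 ± 1.2 (adjusted p = 0.00193), but 1 library decided its size. LN30 replicate 3 held 389 CPM beside 4.22 to 13.2 CPM in the others, and without it the log2 fold change was 1.88. limma-voom did not call this gene (3.15). CNAG_04468 went from 576 ± 313 to 11.1 ± 4.55 CPM (-5.69 ± 0.48, adjusted p = 3.22e-06) and CNAG_06554 from 1340 ± 765 to 33.9 ± 13.9 CPM (-5.30 ± 0.51, adjusted p = 5.9e-06).

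The edgeR quasi-likelihood test called 3254 of 6884 genes at 30 °C, 1402 of them higher and 1852 lower in low nitrogen. Of these, 651 rose and 672 fell at least 2-fold. The replicates at 30 °C varied more than those at 37 °C (biological coefficient of variation 0.303 against 0.166), while the test used 1 shared estimate of the spread. In data simulated with these spreads and 200 changed genes, 31.4% of the calls of this comparison were false (80 genes). Fitting the 30 °C libraries alone gave 5.48% (8 genes) in the simulation and called 2286 genes in the real data. With only 200 changed genes simulated, these shares do not carry over to the real data, where far more genes were called. The simulated genes also varied independently, without the variation that genes shared within the real groups.

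At 37 °C the same question was asked of LN37 against HN37. Both ammonium permeases were again higher in low nitrogen. CNAG_00235 went from 140 ± 11.7 (n = 3) to 376 ± 32.5 CPM (n = 4), a log2 fold change of 1.42 ± 0.31 (adjusted p = 0.014). CNAG_04758 went from 26.8 ± 2.64 to 204 ± 44.4 CPM, 2.93 ± 0.53 (adjusted p = 0.00446). The call of CNAG_00235 ended without HN37 replicate 1 (1.36) or 2 (1.39), whereas that of CNAG_04758 stood in each leave-one-out fit. These were the 2 of 9 nitrogen loci that passed, also when adjusted over these 9 alone, while CNAG_04307 (-0.54 ± 0.21) missed over all genes and passed when adjusted over its list of 2 catabolism loci. The NADP-dependent dehydrogenase CNAG_01577 had 0.64 ± 0.42 (adjusted p = 0.358), the regulator CNAG_00193 0.36 ± 0.19 (adjusted p = 0.251), and the laccases CNAG_03465 and CNAG_03464 0.66 ± 0.33 and 0.69 ± 0.37 (adjusted p = 0.214 and 0.256). Fitted on the 37 °C libraries alone, all 4 of these loci were called higher in low nitrogen (0.64, 0.37, 0.67 and 0.70), as was CNAG_00879 (0.45), and CNAG_04307 was called lower, as it was by DESeq2 (-0.56).

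Ergosterol synthesis had 2 of 8 loci lower in LN37 and none higher, over all genes and adjusted over the list alone, and the fit of the 37 °C libraries alone also called CNAG_06829 lower (-0.94). CNAG_00519 went from 486 ± 99.4 to 211 ± 14.3 CPM (-1.2 ± 0.20, adjusted p = 0.00262), and its call stood without any 1 library. CNAG_01737 had -1.16 ± 0.28 (adjusted p = 0.02), a call that ended without HN37 replicate 1 (-1.15) or 2 (-1.12) or LN37 replicate 3 (-1.07) or 4 (-1.04). One of 6 capsule loci, CNAG_03322, was called (-0.59 ± 0.17, adjusted p = 0.0391). That call ended with upper-quartile scaling (-0.51), with the replicate block (-0.60), and without HN37 replicate 1 (-0.53), 2 (-0.63) or 4 (-0.60) or LN37 replicate 1 (-0.50), 3 (-0.54) or 4 (-0.51). No list passed camera at 37 °C. The lowest adjusted p was 0.059, for ergosterol synthesis and for iron and copper uptake (adjusted p = 0.596 with an estimated correlation for both), and 2 of 5 lists had an unadjusted p under 0.05. The rotation test fry also called none, with a lowest adjusted p of 0.153. Iron and copper uptake passed camera without HN37 replicate 4 (0.0258) or LN37 replicate 1 (0.0444), 3 (0.0204) or 4 (0.0498), and ergosterol synthesis without LN37 replicate 1 (0.0386). The highest leave-one-out value of both lists was 0.104. With genes of a mean CPM of 10 or more, both lists passed (0.0433 and 0.0457).

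Both efflux transporters were lower in LN37. CNAG_00796 fell from 298 ± 52.8 to 115 ± 17.2 CPM (-1.38 ± 0.26, adjusted p = 0.00601). CNAG_00730 had -0.81 ± 0.23 (adjusted p = 0.0358), and its call ended with upper-quartile scaling (-0.72) and without HN37 replicate 1 (-0.90), 2 (-0.64) or 4 (-0.86) or LN37 replicate 1 (-0.73), 3 (-0.74) or 4 (-0.71). Of the iron and copper loci, 2 of 8 fell over all genes and adjusted over the list alone, and the fit of the 37 °C libraries alone also called CNAG_01653 lower (-1.65). The metallothionein CNAG_00306 had -1.07 ± 0.30 (adjusted p = 0.0346), and its call ended without HN37 replicate 1 (-1.04) or 2 (-0.98) or LN37 replicate 1 (-1.0), 2 (-1.09), 3 (-1.16) or 4 (-0.91). The copper transporter CNAG_07701 had -0.67 ± 0.17 (adjusted p = 0.0257), and its call ended with upper-quartile scaling (-0.59) and without HN37 replicate 1 (-0.70) or 2 (-0.63) or LN37 replicate 1 (-0.59), 2 (-0.61) or 4 (-0.59). The superoxide dismutase CNAG_01019 missed the threshold over all genes (0.79 ± 0.25, adjusted p = 0.0543) and passed when adjusted over the list alone. DESeq2 (0.77) and limma-voom (0.84) called it.

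No chaperone, mating or phospholipase locus on the lists was called at 37 °C over all genes or adjusted over the list alone, although the fit of the 37 °C libraries alone called the phospholipase CNAG_06085 (-0.53). Of 9 tested mitochondrial genes, CNAG_09007 was higher in LN37 (1.44 ± 0.35, adjusted p = 0.0201), a call that ended without HN37 replicate 1 (1.10) or 2 (1.63) or LN37 replicate 3 (1.21) or 4 (1.47). Most of these 9 genes lay at a few CPM or less. Among genes without a named product, CNAG_01118 rose from 28.6 ± 3.98 to 373 ± 113 CPM (3.71 ± 0.60, adjusted p = 0.00249), and CNAG_07448 from 46.4 ± 8.27 to 497 ± 145 CPM (3.42 ± 0.38, adjusted p = 0.000297). CNAG_04417 went from 979 ± 320 to 80.4 ± 36.2 CPM (-3.61 ± 0.39, adjusted p = 0.000297) and CNAG_07897 from 56.4 ± 30.1 to 7.57 ± 3 CPM (-2.90 ± 0.34, adjusted p = 0.000401). At 30 °C, CNAG_07448 also rose (4.22 ± 0.35), CNAG_04417 also fell (-2.39 ± 0.36), and CNAG_07897 did not pass the test (0.11 ± 0.30).

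At 37 °C the test called 690 genes, 265 higher and 425 lower, and 71 and 170 at least 2-fold. The 37 °C libraries alone gave 2091 genes (973 higher), and in simulated data the shared fit recovered 61% of 2-fold changes against 92%. The count was 233 without HN37 replicate 1, 186 without HN37 replicate 2, and 210, 327 and 183 without LN37 replicates 1, 3 and 4. DESeq2 called 1124 genes, and a block for the letter in the sample titles gave 383.

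The interaction asks whether the response to low nitrogen differed between the cultures at 37 °C and 30 °C. The ammonium permease CNAG_00235 responded less at 37 °C, with a difference of log2 fold changes of -1.44 ± 0.41 (adjusted p = 0.0157). The difference at CNAG_04758 did not pass (-1.0 ± 0.65, adjusted p = 0.245), but was called without HN30 replicate 4 (-2.05) and with the main within-group axis as a covariate (-1.28). The NAD-dependent dehydrogenase CNAG_00879 differed by 1.99 ± 0.39 (adjusted p = 0.00291) and urate oxidase CNAG_04307 by -1.91 ± 0.28 (adjusted p = 0.00109). The laccase CNAG_03465 differed by -1.94 ± 0.44 (adjusted p = 0.00531), and the other laccase, CNAG_03464, did not pass (-0.75 ± 0.51). Responses of opposite sign, each past the test at both temperatures, were found for the efflux transporter CNAG_00730 (0.83 at 30 °C and -0.81 at 37 °C) and the metallothionein CNAG_00306 (0.93 and -1.07). Their interactions were -1.63 ± 0.31 (adjusted p = 0.00252) and -2.01 ± 0.41 (adjusted p = 0.00336).

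Of the 41 fixed loci outside the mitochondrial genome, 14 differed between temperatures, both over all genes and when adjusted over these 41 together. They included 3 of 9 nitrogen loci, 2 of 8 ergosterol loci (CNAG_00854 at 2.97 ± 0.52 and CNAG_03819 at 1.95 ± 0.42), both efflux loci and 1 of 2 superoxide dismutases. In the iron and copper list 3 of 8 differed, and 5 when adjusted over the list alone, as did the pheromone receptor CNAG_06808 when tested as a list of 1. In the capsule list CNAG_02885 differed (1.22 ± 0.37, adjusted p = 0.0204). Its call and those of the metallothionein CNAG_05449 and the phospholipase CNAG_06085 ended without HN37 replicate 2 (0.98, -2.64 and -1.15), and CNAG_05449 had -4.1 without HN30 replicate 3 in place of -2.95. The dehydrogenase CNAG_01577 did not pass (-1.36 ± 0.57, adjusted p = 0.076), but was called by DESeq2 (-1.41) and limma-voom (-1.69) and without HN30 replicate 3 (-1.05) or 4 (-1.90). Without HN30 replicate 3, the urease locus CNAG_05540 (-0.70) and the ergosterol loci CNAG_00040 (1.12) and CNAG_00519 (0.85) were called too. The same fit called the capsule locus CNAG_07554 (0.66), the siderophore transporter CNAG_00815 (-1.69) and the receptor CNAG_06808 (-0.81). Without LN30 replicate 3, CNAG_00815 (-1.36) and the copper transporter CNAG_00979 (-0.90) were called. No list passed camera, with a lowest adjusted p of 0.235 (adjusted p = 0.978 with an estimated correlation) and 1 of 5 lists under an unadjusted 0.05. The fry test also called none (lowest adjusted p = 0.293).

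**Figure D3:**
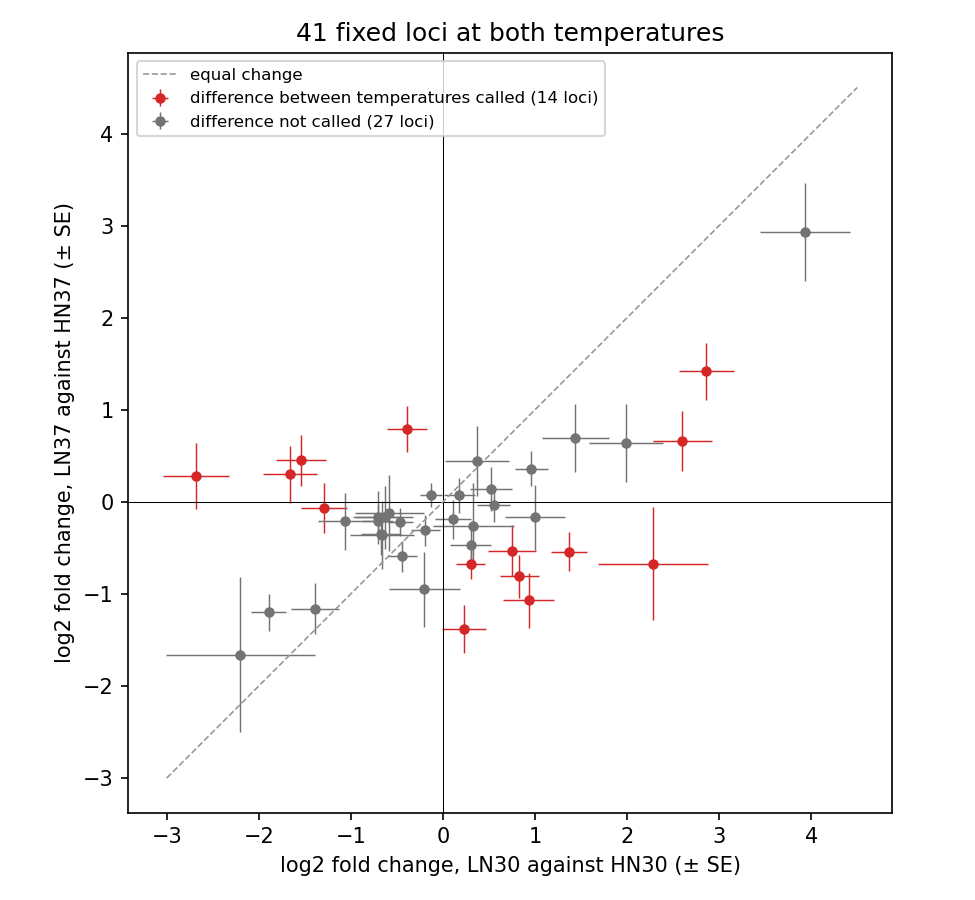
Log2 fold change in low nitrogen (± SE) of 41 fixed loci at 30 °C (x axis) and 37 °C (y axis), with the 14 loci whose responses differed in the interaction test in red and the other 27 in grey. The ammonium permeases lie high on both axes (2.86 and 1.42 for CNAG_00235), whereas the efflux transporter CNAG_00730 rose at 30 °C and fell at 37 °C, the latter call ending with upper-quartile scaling.

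Genes without a named product were led by CNAG_01075 (4.45 ± 0.49) and CNAG_06332 (1.64 ± 0.19), whose responses were more positive at 37 °C, and by CNAG_03838 (-2.88 ± 0.32) and CNAG_01171 (-1.67 ± 0.19), all with adjusted p = 0.000389. CNAG_01075 fell at 30 °C (-2.06 ± 0.32) and rose at 37 °C (2.39 ± 0.37). Its levels were low, at 12.4 ± 5.06 CPM in HN30, 2.97 ± 0.69 in LN30, 1.12 ± 0.321 in HN37 and 5.95 ± 2.01 in LN37. In all, 2300 genes differed, 1251 with a more positive and 1049 with a more negative response at 37 °C. More genes passed in the same direction at both temperatures than independent lists would share, 96 against 54 for rising and 149 against 114 for falling genes. Opposite calls were fewer than such lists would share, 51 against 86.6 and 22 against 71.3. The log2 fold changes at the 2 temperatures correlated at r = 0.15 across genes, which are not independent replicates. The count was 3574 without HN30 replicate 3 and 1405 without HN37 replicate 2.

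The last pair of comparisons set cultures at 37 °C and 28 h against cultures at 30 °C and 38 h, first in high nitrogen. Of the ergosterol loci 7 of 8 were higher at 37 °C, and 8 of 8 when adjusted over the list alone. CNAG_00854 rose by a log2 fold change of 1.80 ± 0.36 (adjusted p = 0.00503) and CNAG_06644 by 1.12 ± 0.21 (adjusted p = 0.00315). As a list it had a camera adjusted p of 6.78e-06, but adjusted p = 0.206 with an estimated correlation. In the capsule list 3 of 6 rose, and 4 when adjusted over the list alone, with a camera adjusted p of 0.00567 (adjusted p = 0.319 with an estimated correlation). The chaperone CNAG_06443 rose from 829 ± 82.8 to 2980 ± 1370 CPM (1.85 ± 0.29, adjusted p = 0.00102), while the chaperone CNAG_06150 had -0.13 ± 0.38 (adjusted p = 0.832).

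Several of these calls ended when 1 library was left out, although most log2 fold changes stayed close to their main values. With all libraries CNAG_00519 had 0.67 and CNAG_06829 had 1.42. Without HN37 replicate 1 the ergosterol calls of CNAG_00040 (1.11), CNAG_00519 (0.72), CNAG_01737 (1.04) and CNAG_06829 (1.46) ended, as did the capsule calls of CNAG_00600 (0.60), CNAG_04969 (0.63) and CNAG_07554 (0.60). The calls of CNAG_00519 (0.50) and CNAG_06829 (1.28) also ended without HN37 replicate 2, and that of CNAG_06829 without HN37 replicate 4 (1.56). The calls of CNAG_07554 and CNAG_04969 each ended in further leave-one-out fits, among them those without HN37 replicate 2 (0.64 and 0.81) or 4 (0.57 and 0.74). That of CNAG_07554 also ended without HN30 replicate 2 (0.62), and that of CNAG_04969 without HN30 replicate 1 (0.77), 3 (0.53) or 4 (0.70). The calls of CNAG_00854, CNAG_06644, CNAG_06534 and the chaperone CNAG_06443 stood in every leave-one-out fit. When only the high nitrogen libraries were fitted, CNAG_00854 and CNAG_06644 were the ergosterol calls that stood, and all 3 capsule calls ended. The ergosterol locus CNAG_03819 and the capsule locus CNAG_02885 passed when adjusted over their lists and not over all genes, but several alternatives called them over all genes, DESeq2 among them (0.91 and 0.76). CNAG_03819 was also called without HN30 replicate 3 (0.60) or 4 (1.03), and CNAG_02885 without HN30 replicate 4 (0.88) or HN37 replicate 2 (0.94).

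In high nitrogen 3 of 8 iron and copper loci were higher at 37 °C, namely the copper transporters CNAG_00979 (1.46 ± 0.24, adjusted p = 0.00117) and CNAG_07701 (0.97 ± 0.17, adjusted p = 0.00234) and the metallothionein CNAG_00306 (1.22 ± 0.30, adjusted p = 0.0139), the last not without HN37 replicate 1 (1.17). That list had a camera adjusted p of 0.0368 and adjusted p = 0.319 with an estimated correlation. Of the 9 nitrogen loci 1 rose, CNAG_04307 (1.17 ± 0.21, adjusted p = 0.002), and 1 fell, CNAG_00879 (-1.27 ± 0.29, adjusted p = 0.0097), the latter not without HN37 replicate 1 (-1.17). The superoxide dismutase CNAG_04388 had -1.62 ± 0.43 (adjusted p = 0.0198), and its call ended without HN37 replicate 1 (-1.66), 2 (-1.53) or 4 (-1.63), and it had -1.04 without HN30 replicate 3. No laccase, efflux, mating, phospholipase or mitochondrial gene of the lists passed, although CNAG_09012 was called lower without HN30 replicate 2 (-2.21). Without HN30 replicate 4 the laccase CNAG_03465 (0.97) and the permeases CNAG_00235 (0.84) and CNAG_04758 (1.41) were called higher at 37 °C. The metallothionein CNAG_05449 was called without HN30 replicate 3 (1.97) and the dismutase CNAG_01019 without HN37 replicate 2 (0.74). Among genes without a named product, CNAG_02060 (2.84 ± 0.37) and CNAG_06817 (2.66 ± 0.46, or 3.41 without HN30 replicate 4) rose most. The genes that fell most were CNAG_04469 (-6.02 ± 0.64, or -6.75 without HN37 replicate 2) and CNAG_04470 (-5.39 ± 0.67).

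In high nitrogen 1246 genes differed, 530 higher and 716 lower at 37 °C, with 176 and 397 at least 2-fold. Upper-quartile scaling moved the median log2 fold change of all genes from -0.01 to 0.127 and the share of calls that were higher from 42.5% to 59.4%. The count fell to 250 when only these libraries were fitted, to 753 with the replicate block, and to 485 or 509 without HN37 replicate 1 or 4, and a different split of the same libraries called 1509 genes.

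In low nitrogen the same contrast of 37 °C with 30 °C gave the most calls of the 5 comparisons. Ergosterol loci rose again, 7 of 8 over all genes and adjusted over the list alone, led by CNAG_00854, from 10.7 ± 5.35 to 290 ± 21.5 CPM (4.76 ± 0.40, adjusted p = 1.35e-06), and by CNAG_03819 (2.84 ± 0.30, adjusted p = 7.23e-06). The list had a camera adjusted p of 0.000901 and adjusted p = 0.505 with an estimated correlation. In the capsule list 5 of 6 loci rose, led by CNAG_02885 (1.96 ± 0.26, adjusted p = 2.68e-05), with a camera adjusted p of 0.0207 and adjusted p = 0.555 with an estimated correlation. The chaperone CNAG_06443 rose by a log2 fold change of 2.39 ± 0.28 (adjusted p = 1.29e-05) and the superoxide dismutase CNAG_01019 by 1.67 ± 0.23 (adjusted p = 3.58e-05), whereas the dismutase CNAG_04388 had -1.16 ± 0.38 (adjusted p = 0.0155, a call that ended without LN30 replicate 4, at -0.76). The chaperone CNAG_06150 had -0.06 ± 0.35 (adjusted p = 0.895).

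**Figure D4:**
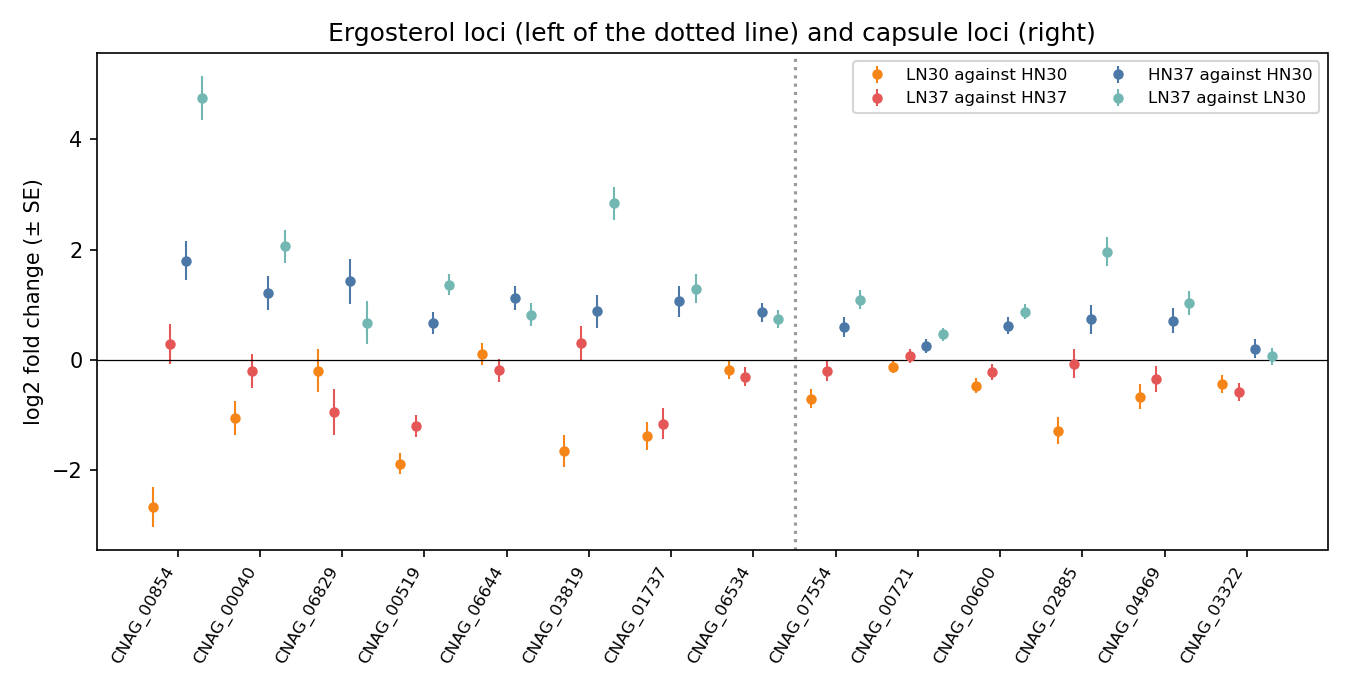
Log2 fold change (± SE, y axis) of 8 ergosterol synthesis and 6 capsule loci (x axis) in 4 comparisons, low against high nitrogen at 30 °C and 37 °C and 37 °C against 30 °C in high and low nitrogen. CNAG_00854 had -2.68 in low nitrogen at 30 °C and 4.76 in low nitrogen at 37 °C against 30 °C, while capsule loci changed less.

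Among the nitrogen loci 5 of 9 were lower at 37 °C in low nitrogen and 1, CNAG_00879, was higher (0.72 ± 0.26, adjusted p = 0.0257). All 5 lower calls ended with upper-quartile scaling, namely those of the permease CNAG_00235 (-0.89 to -0.59), CNAG_01577 (-1.0 to -0.70), CNAG_00193 (-0.61 to -0.31), CNAG_04307 (-0.74 to -0.44) and urease CNAG_05540 (-0.66 to -0.36). Both efflux loci were lower (CNAG_00730 at -1.38 ± 0.21 and CNAG_00796 at -1.2 ± 0.25), as were the laccase CNAG_03465 (-1.37 ± 0.30) and the phospholipase CNAG_06085 (-1.46 ± 0.27). Of the iron and copper loci 2 of 8 rose and 3 fell, led by the metallothionein CNAG_05449 (-2.13 ± 0.60, adjusted p = 0.00609) and the siderophore transporter CNAG_00815 (-1.59 ± 0.34, adjusted p = 0.000872). The pheromone receptor CNAG_06808 had -0.46 ± 0.18, or -0.16 with upper-quartile scaling, which ended its call. The mitochondrial genes CNAG_09000 (-2.29 ± 0.86) and CNAG_09012 (-2.33 ± 0.75) were called lower over all genes and not when adjusted over the list alone, and both calls ended without LN30 replicate 3 (-1.04 and -1.66). That of CNAG_09000 also ended without LN37 replicate 1 (-2.04), 2 (-2.22) or 3 (-2.03) and with upper-quartile scaling (-1.98).

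The other calls of this comparison that 1 library ended were those of 4 nitrogen loci, 2 iron and copper loci and the pheromone receptor. CNAG_00235 lost its call without LN30 replicate 3 (-0.63), CNAG_05540 without LN30 replicate 4 (-0.53) or LN37 replicate 1 (-0.59) or 2 (-0.62), and CNAG_00879 without LN30 replicate 1 (0.59), 2 (0.63) or 4 (0.65). CNAG_01577 lost it in 6 of 8 fits, with values from -0.88 without LN30 replicate 3 to -1.01 without LN37 replicate 2. The metallothionein CNAG_00306 (-0.79 ± 0.28, adjusted p = 0.0224) lost it without LN30 replicate 1 (-0.62) or LN37 replicate 1 (-0.72) or 4 (-0.63), and with upper-quartile scaling (-0.49). The iron permease locus CNAG_06242 (0.77 ± 0.31, adjusted p = 0.042) lost it without LN30 replicate 2 (0.81) or LN37 replicate 1 (0.84), 2 (0.74), 3 (0.83) or 4 (0.81), and with RLE scaling (0.74), and had 0.47 without LN30 replicate 3. The pheromone receptor CNAG_06808 lost it without any library but LN30 replicate 4, with values from -0.40 to -0.46. Without LN30 replicate 3 the ergosterol locus CNAG_06829 (1.35) and the locus CNAG_01653 (-1.51) were called.

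Among genes without a named product, CNAG_07869 rose most after the ergosterol locus CNAG_00854, from 0.751 ± 0.574 to 18.2 ± 5.87 CPM (4.62 ± 0.68, adjusted p = 5.94e-05). CNAG_07912 went from 204 ± 127 to 6.05 ± 1.2 CPM (-5.08 ± 0.93, adjusted p = 0.000304) and CNAG_00848 from 14100 ± 7600 to 517 ± 118 CPM (-4.77 ± 0.92, adjusted p = 0.000437). In low nitrogen 4376 genes differed, 2204 higher and 2172 lower at 37 °C, with 1083 and 1151 at least 2-fold. With upper-quartile scaling the median log2 fold change of all genes was 0.302 in place of 0, and 65.6% of calls were higher in place of 50.4%.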

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

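Of the tests given here, those chosen only after the result was seen were the position between HN30 and LN30, the correlation with LN30 minus LN37, the tests of transcript entries beyond 15, and the use of the counts without 1 HN30 library and of the fits of each temperature alone, both planned as alternatives, to explain the gap in counts.

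More genes were called for low nitrogen at 30 °C than at 37 °C, 3254 against 690. The lowest 30 °C count with 1 HN30 library left out was 2794, so a smaller high nitrogen group did not bring that count near 690. This does not show how far the 37 °C count depends on the size of HN37. With 1 library left out the 37 °C count was 183 to 564, so the part of the smaller group stays open. A shared estimate of the spread may account for most of the gap in counts, because fits of each temperature alone called 2286 and 2091 genes, a ratio of 1.09 in place of 4.72. Changes were nonetheless larger at 30 °C, where the SD of log2 fold changes net of their errors was 0.77 against 0.48 over 6387 genes, and the ratio stayed at 1.41 or more without any 1 library. A stronger response at 30 °C may come from temperature or from the longer culture, which this design changes together.

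HN30 replicate 3 stood apart from its group and gave 10 of the 26 single-library extremes described below. A mislabelled low nitrogen library is argued against by its position of -0.76 on the 690 genes called at 37 °C, where 0 is the mean of the other HN30 libraries (SD 0.51) and 1 that of LN30, whereas HN30 replicate 4 lay at 0.56, close to LN30 replicate 4 (0.62), with its permease CNAG_04758 at 52.6 CPM nonetheless below the LN30 libraries (230 to 363). The part of a few abundant genes stays open, since its deviations correlated with those of HN37 replicate 2 at 0.53 across genes both with and without the 69 most abundant, too few of 6884 equally weighted genes to move that value. Its deviations correlated at 0.69 across genes with LN30 minus LN37, and those of HN37 replicate 2 at 0.66. The other HN30 and HN37 libraries had negative values, from -0.26 in HN30 replicate 1 to -0.64 in HN30 replicate 4. Each deviation was taken from the mean of the other libraries of its group, so these values are not independent. LN30 and LN37 differ in temperature as well as culture time, so the correlation does not single out culture stage. A candidate explanation is that flasks were harvested at different stages of the culture, a hypothesis formed on these libraries.

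Among entries with a q-value under 0.05, the authors' deposited table held 36 transcript entries with log2 fold changes beyond 15 in either direction. Of these, 23 were at 30 °C and 13 at 37 °C, and 35 of them belonged to loci with several transcripts. Over these 35 entries the whole gene's counts had a median absolute log2 fold change of 0.44 and a highest of 1.73, which argues against whole genes switched on or off by nitrogen there, and 13 entries were called at gene level. Reads assigned to different transcripts of 1 gene in different libraries may account for them. For the remaining entry, CNAG_00859 with 1 transcript, the whole gene's log2 fold change was 10.94 (adjusted p = 0.0777), but 1 of 4 LN30 libraries held it (46 CPM, with 0 in the other 30 °C libraries), as did HN37 replicates 2 and 4 (14.8 and 21.3 CPM) and LN37 replicate 4 (27.2), which argues against a switch by nitrogen. No biological explanation was tested for a switch between transcripts.

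The response to low nitrogen differed between temperatures in 2300 genes by the interaction test. Of the fixed loci and the genes chosen by rule, those that passed it with a more positive response at 37 °C were the ergosterol loci CNAG_00854 (2.97) and CNAG_03819 (1.95), CNAG_00879 (1.99), the capsule locus CNAG_02885 (1.22), the dismutase CNAG_01019 (1.18), CNAG_04468 (5.28), CNAG_04470 (4.74), CNAG_01075 (4.45), CNAG_06554 and CNAG_04469 (3.85 each), CNAG_07869 (2.54) and CNAG_06332 (1.64). Those with a more negative response were the permease CNAG_00235 (-1.44), urate oxidase CNAG_04307 (-1.91), laccase CNAG_03465 (-1.94), phospholipase CNAG_06085 (-1.29), copper transporter CNAG_07701 (-0.97), metallothioneins CNAG_05449 (-2.95, or -4.1 without HN30 replicate 3) and CNAG_00306 (-2.01), and efflux transporters CNAG_00730 (-1.63) and CNAG_00796 (-1.61). Among genes without a named product they were CNAG_01118 (-3.71), CNAG_07897 (-3.01), CNAG_03838 (-2.88), CNAG_06817 (-2.56) and CNAG_01171 (-1.67).

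The libraries were also split into groups in other ways. For low nitrogen at 30 °C, 1 of 35 splits, the real one, gave 3254 genes or more, and the highest other gave 1860, with HN30 replicate 3 and LN30 replicate 4 exchanged. At 37 °C, 1 of 35 splits reached 690, with 22 the highest other. For the interaction 1 of 100 drawn splits reached 2300, with 1590 the highest other, and for temperature in low nitrogen 1 of 35 reached 4376, with 0 the highest other. For the low nitrogen counts at each temperature and the temperature count in low nitrogen, chance can be excluded at 0.05. This holds for each count taken alone, without adjustment over the comparisons. The interaction splits exchanged nitrogen labels within each temperature, which also removes the nitrogen response itself. They cannot decide whether the responses differed between temperatures by chance. The highest other split there kept the true 30 °C grouping with its labels reversed. For temperature in high nitrogen 2 of 35 splits reached 1246. The other called 1509 and set HN30 replicate 4 with the HN37 libraries against the rest of HN30, so chance cannot be excluded for that count, and the split points to a structure within HN30.

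In 26 of 186 sets of 4 libraries, 1 library lay far from the other 3 by Dixon's ratio. Chance passes this test in about 5% of sets of normally distributed values. CPM were tested without logs, and the sets reuse the same libraries and are not independent. The 26 cases therefore cannot be set against that share as separate events. HN37, with 3 libraries, was not tested. HN30 replicate 3 was the lowest of its group for the ergosterol loci CNAG_00854 (28.2 CPM, others 79.5 to 84.5), CNAG_03819 (63.7, others 206 to 234) and CNAG_06829 (34.6, others 84.2 to 91.8). It was the highest for CNAG_00848 (33700 CPM, others 972 to 4800), CNAG_07912 (159, others 4.63 to 13.2), phospholipase CNAG_06085 (607, others 220 to 275), siderophore transporter CNAG_00815 (634, others 215 to 266), metallothioneins CNAG_05449 (1900, others 201 to 420) and CNAG_00306 (703, others 328 to 369), and dismutase CNAG_04388 (799, others 225 to 306).

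LN30 replicate 3 was the highest of its group for 8 loci. They were CNAG_06312 (389 CPM, others 4.22 to 13.2), CNAG_07912 (394, others 120 to 161), CNAG_00879 (485, others 220 to 255), glutamate synthase CNAG_04862 (244, others 49.7 to 74.2), the capsule loci CNAG_07554 (132, others 108 to 112) and CNAG_00721 (176, others 143 to 148), laccase CNAG_03464 (11, others 4.4 to 5.11) and the chaperone CNAG_06443 (692, others 418 to 460). HN30 replicate 4 was the highest for CNAG_06817 (88.8 CPM, others 19.2 to 26.3), the permease CNAG_04758 (52.6, others 9.21 to 10.9) and laccase CNAG_03465 (30.3, others 13 to 14.1). The remaining cases were CNAG_01075 in HN30 replicate 1 (19.9 CPM, others 8.85 to 10.5), CNAG_00854 in LN30 replicate 4 (18.7, others 7.48 to 8.5), CNAG_04417 and CNAG_03838 in LN37 replicate 2 (134, others 60.5 to 65.9, and 15.4, others 13.2 to 13.5), and the copper transporter CNAG_07701 in LN37 replicate 3 (35.3, others 24.7 to 25.7).

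The authors' deposited table also held 53 entries without a locus tag, which no comparison here used. Of these, 10 had a q-value under 0.05 at 30 °C, and 1 at 37 °C. The entry mRNA_19 had -2.59 (q = 2.51e-12) and mRNA_20 had -2.83 (q = 3.58e-11) at 30 °C, and mRNA_48 had -1.62 (q = 0.000229) at 37 °C, negative values in the authors' deposited table being higher in low nitrogen.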

How the results depend on the processing

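Alternatives chosen only after the data were seen were the 16 columns as deposited, the other number and letter of the merged library, the within-group axis, leaving out both doubted libraries, and a spread per group. The counts for low nitrogen at 30 °C (3254) and for temperature in low nitrogen (4376) stayed within 1.5 times in every alternative but the fold threshold, at 2286 to 4227 and 3923 to 4916 over the alternatives run. With a fold change of 2 or more, which narrows every list by construction, the 5 counts were 1323, 241, 1465, 573 and 2234 in the order of the text.

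Counts that moved by over 1.5 times, apart from those with a block or with 1 library left out, which are given after these, were the following. For low nitrogen at 37 °C (690), DESeq2 called 1124, the libraries compared alone 2091, limma-voom with a spread per group 1785, the 16 columns 1154, and the within-group axis as a covariate 2109. For temperature in high nitrogen (1246), the libraries compared alone gave 250, a spread per group 516 and the axis 2597. For the interaction (2300) the axis gave 3510. The fits alone and with a spread per group differ from the main one by construction in whose spread they use. For the other settings the cause was not tested.

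The data did not show that library numbers pair the samples, as same-number correlations of deviations ran from -0.31 to 0.41, but pairing is not excluded. With the replicate block the counts were 3149, 648, 2333, 753 and 4273, and with the merged library numbered 3 they included 402 at 37 °C and 688 for temperature in high nitrogen. With a block for the title letter they were 2755, 383, 2013, 483 and 4035, and with the merged library lettered D 199 at 37 °C and 538 for temperature in high nitrogen. Among lists, the replicate block with that library numbered 3 called 1 at 37 °C in place of 0.

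Leaving out 1 library gave 2714 to 4044 genes at 30 °C, 183 to 564 at 37 °C, 1405 to 3574 for the interaction, 485 to 1816 and 3957 to 4270 for temperature in high and low nitrogen, and 0 to 2 lists at each temperature. Lists at 30 °C (1) were 0 with an estimated correlation and 2 with fry, with the axis, or without both doubted libraries. At 37 °C (0) they were 2 with a mean CPM of 10 or more and 2 without both doubted libraries. Without both, the gene counts were 4102, 844, 3088, 1221 and 4854.

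Of 269 values of named loci, DESeq2 kept 258 on their side of the threshold and in direction, limma-voom 261, RLE scaling 267, and upper-quartile scaling 254. The libraries compared alone, not run for the interaction and so with fewer values, kept 182, ended 19 and added 13. Reversals were 2 mitochondrial genes near the floor in low nitrogen at 30 °C, neither called in the main comparison. CNAG_09004 had -0.04, ran from -0.45 to 1.77 with 1 library left out, and had 1.80 without both doubted libraries. CNAG_09009 had -0.14, ran from -0.45 to 1.00, and had 1.04 without both, and HN30 replicate 3 was the library that turned each. The cause was not tested. Lists that need product descriptions were not run, nor was the fit of only the libraries compared for the interaction, which uses all groups. Depth limits the mitochondrial genes and others under a few CPM.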

Other observations

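Neighbouring genes changed together in low nitrogen at 30 °C, a pattern first seen for falling genes, whose test was therefore chosen after the result, and then tested for rising genes. The steepest run was CNAG_04467 to CNAG_04472, 6 adjacent loci that all fell, with log2 fold changes of -3.67 to -5.69. Their expression was highest in HN30. CNAG_04467 stood at 681 CPM in HN30, 17.6 in LN30, 36.2 in HN37 and 15.7 in LN37, and CNAG_04469 at 1130, 48.7, 17.4 and 10.8. A second run, CNAG_06554 to CNAG_06557, held 4 loci with -2.91 to -5.30, again highest in HN30, with CNAG_06557 at 817 CPM beside 75.3, 22.5 and 30.7. The HN30 level varied between libraries, and replicate 4 was the lowest for the run members examined per library. It held 138 CPM of CNAG_04468 (others 594 to 868), 299 of CNAG_04469 (others 1200 to 1730), 132 of CNAG_04470 (others 582 to 829) and 292 of CNAG_06554 (others 1410 to 2130). All 10 loci differed in the interaction test, and none passed the low nitrogen test at 37 °C in the fit of all libraries. The 37 °C libraries fitted alone called 5 of them lower, CNAG_06554 (-1.44), CNAG_04467 (-1.2), CNAG_04471 (-0.82), CNAG_04468 (-0.41) and CNAG_06555 (-0.38).

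Other runs that fell at 30 °C were shallower. CNAG_02100 to CNAG_02094 held 6 loci at -1.03 to -2.04, CNAG_02196 to CNAG_02193 held 4 at -1.08 to -2.54, CNAG_03323 to CNAG_03326 held 4 at -1.15 to -2.10, and CNAG_06860 to CNAG_07979 held 4 at -1.03 to -1.45. Within them CNAG_07399 (-1.65, adjusted p = 0.00347) and CNAG_02096 (-1.45, adjusted p = 0.0192) also fell at 37 °C. In the fit of the 37 °C libraries alone CNAG_02194 (-0.79) and CNAG_02100 (-0.59) fell too, and CNAG_02195 (0.53) and CNAG_03323 (0.54) rose. These loci were chosen after their values were seen.

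At 30 °C, 117 adjacent pairs both fell at least 2-fold, against a mean of 65.5 and a highest of 93 in 10000 shuffled gene orders (one-sided permutation p = 1e-04, the smallest these shuffles can give, and 4e-04 adjusted over 4 tests). Among rising genes 87 adjacent pairs compared with a mean of 61.4 and a highest of 92 (permutation p = 9e-04, adjusted 0.0018). Adjacency was counted among the tested protein-coding genes, so other genes may lie between the members of a pair. At 37 °C there were 7 falling pairs against 4.16 (permutation p = 0.125) and 4 rising pairs against 0.704 (permutation p = 0.0054, adjusted 0.0072). Chance placement along the chromosomes is thus argued against for both directions at 30 °C. Rising genes at 37 °C passed the same test, although with only 4 pairs. Shared regulation, reads of overlapping neighbours and related adjacent genes may each contribute, and the files name neither strand nor products to separate them.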
